A study of Mus musculus with 31 samples.

How the data were processed

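RNA from 20000 sorted cells per sample was amplified, labelled and hybridised to Affymetrix mouse whole-transcript gene arrays. Lineage antibodies, cKit, Sca1, Flk2, CD48, CD150, Fc gamma receptor, CD34, Mac1 and Gr1 defined the 9 populations, and the labels state that replicates are biological. They give no sex, animal or pool of animals, and stem cell and GMP arrays also served as controls in a related study. The deposited values are log2 values that the authors made by RMA, whose version they did not state. They range from 1.39 to 14.29. Arrays of 1 population correlated at 0.96 to 0.996 across genes.

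The table holds 35557 probes. Of these, 21789 pair with 1 gene, 1621 with several and 12147 with none in the probe annotation. For 21698 of the first kind the gene identifier matched the gene reference used for current symbols, and 91 did not match. The brightest probe stood for each of the 999 genes with more than 1, which left 19938 genes. Probes of several genes or none entered only the alternative that tests all probes. Probe positions were not used here.

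Linear models were fitted to all 31 arrays with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per population, contrasts.fit, eBayes), with 22 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, from limma's moderated two-sided test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 11 comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 22 lists comprise 17 expression programmes and 5 lists of markers of other cells. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 242 tests. The set-adjusted fit called 98 of these, and 33 with the correlation estimated from the data.

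The deposited arrays fell into 5 sets by their medians and by values identical between arrays, where 2 or more such values link a pair of arrays. The labels do not name these sets. Choices made after seeing this were a set block in the planned fit, and the set-adjusted fit on quantile-normalized values with the set as a block (18 residual degrees of freedom). Others were fits within 1 set, leaving each array out of the set-adjusted fit, and naming genes from the set-adjusted and quantile-normalized fits together. Each set block assumes that a set shifts a gene alike in every population of the set.

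The naming rule took, in each comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes whose groups do not overlap, up to 4 called members of each list, and the sort markers. Predicted and unnamed genes were passed over. Of 173 gene results with the largest changes in the planned fit, 141 were also called in both other fits. For the rises of ST-HSC against LT-HSC this held for 0 of 8, among them S100a9 and Tespa1. A further 21 gene results met the rule but were left out of the report after their values were seen, because the removal of any of 5 to 24 single arrays ended the call. These were Cd27 and Pbk in ST-HSC against LT-HSC, Ddx58, Itga2b, Knl1, Parp14 and Rrm2 in MPP2 against LT-HSC, Hoxb5 in MPP3 against LT-HSC, Cd9 and Vwf in MPP4 against LT-HSC, Itga2b in MPP2 against MPP3, Ctsg, F2r, Gp5 and Zfpm1 in MPP2 against MPP4, Meis1, Rrp9 and Rsad2 in CMP against LT-HSC, and F13a1, Prg2 and S100a8 in GMP against CMP. Each contrast rests on a few arrays, such as LT-HSC 4, that could not be left out, and arrays without weight in it move only its SE. Leaving arrays out therefore says little of how stable the named calls are.

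The fits were tested on simulated data with the set offsets and spreads of the set block model, which favours the set-adjusted fit. Of 100 genes changed 2-fold in each comparison, that fit recovered 43 to 96 percent, and of 100 changed 4-fold 91 to 100 percent. It called 5 to 47 unchanged genes. For ST-HSC against LT-HSC the planned fit called 18834 unchanged genes and the quantile-normalized fit 5900. For PreGr against GMP they called 0 and 1. List tests were simulated for MPP4 against LT-HSC alone, where 5 of 200 lists of 20 unchanged genes passed an unadjusted 0.05. The simulated noise was independent between genes. This share therefore does not show how the list test behaves for genes that vary together, as in the real lists.

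Same-numbered arrays were checked for pairing by the correlation of their residuals across genes. Only in MPP4 against LT-HSC did every pair exceed 0.1, with 0.215 to 0.431 over 4 pairs in the deposited values and 0.132 to 0.27 after quantile normalization. MPP4 and LT-HSC 1 to 3 with different numbers had 0.119 to 0.196 after quantile normalization. Same-numbered arrays of these had -0.0239 to 0.0638 in the set-adjusted fit. The labels state no shared animal or pool for a number, so it entered as a block only in alternatives, and the splits of arrays below were not restricted to pairs. The other alternatives were quantile normalization, centring with and without scaling, a filter on dim genes, trend and robust moderation, the mean of a gene's probes, array weights, fits of the compared populations alone and leaving out each array. A replicate block within replicates 1 to 3 of 6 populations, after quantile normalization, and 1 in the set-adjusted fit of MPP4 against LT-HSC were added after the data were seen.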

Results

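Transcripts were measured on 31 whole-transcript arrays of 9 sorted populations of C57BL/6 mouse bone marrow, from stem cells to granulocytes. The populations were long-term stem cells (LT-HSC, n = 4), short-term stem cells (ST-HSC, n = 3) and the multipotent progenitors MPP2 (n = 3), MPP3 (n = 3) and MPP4 (n = 5). Common myeloid progenitors (CMP, n = 3), granulocyte-monocyte progenitors (GMP, n = 4), pre-granulocytes (PreGr, n = 3) and granulocytes (Gr, n = 3) completed the series. The comparisons ask how the multipotent progenitors differ from stem cells and from each other, and how expression changes along the granulocyte path. The number of arrays per population limits the precision.

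The genes of the sort markers were measured as a check of the labels, not as a finding between the gates they define. After quantile normalization the CD150 gene Slamf1 stood at 8.65 ± 0.56 (log2, mean ± SD) in LT-HSC and 6.83 ± 0.44 in MPP2. It stood at 5.12 ± 0.36 in ST-HSC and 5.60 ± 0.20 in MPP3. Cd48 was at 6.80 ± 0.55 in LT-HSC and 6.89 ± 0.71 in ST-HSC, against 9.84 ± 0.57 in MPP2 and 10.50 ± 0.15 in MPP3. Flt3, which encodes Flk2, was at 11.29 ± 0.56 in MPP4 and 8.15 ± 0.29 in LT-HSC. In ST-HSC, sorted as Flk2 negative, it was at 10.02 ± 0.11. Fcgr3 was at 10.05 ± 0.07 in GMP and 7.39 ± 0.30 in CMP. Itgam, the Mac1 gene, was at 7.56 ± 0.31 in GMP, 10.37 ± 0.17 in PreGr and 11.66 ± 0.41 in Gr. Ly6g, a Gr1 gene, was at 5.32 ± 0.38, 11.24 ± 0.54 and 12.60 ± 0.07 in these. Kit was at 11.36 ± 0.17 in LT-HSC and 8.34 ± 0.24 in Gr, and Cd34 at 11.68 ± 0.04 in CMP and 6.85 ± 0.46 in Gr. The Sca1 gene was not analysed here, because its probe pairs with several genes.

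The deposited values fell into 5 sets of arrays, each with a common level and identical values shared between its arrays. Array medians were 6.19 to 6.22 for LT-HSC 1, 2 and 3 (set 1), and 6.92 on average for LT-HSC 4, MPP3 3, MPP4 4 and 5 and GMP 4 (set 2). They were 7.78 to 7.83 for ST-HSC, MPP2 and MPP3 1 and 2 (set 3), 6.90 to 7.05 for MPP4 1 to 3 and CMP (set 4), and 7.27 to 7.40 for GMP 1 to 3, PreGr and Gr (set 5). Between sets the planned fit called most genes higher in the brighter set. Its counts are given beside those of a fit after quantile normalization, and of a set-adjusted fit that also takes the set as a block. In the set-adjusted fit every comparison with LT-HSC rests on the single array LT-HSC 4, because LT-HSC 1, 2 and 3 form a set of their own. ST-HSC and MPP2 reach the other sets only through MPP3 3 and the mean of MPP3 1 and 2, and CMP reaches LT-HSC only through MPP4. GMP is compared with CMP through GMP 4 alone. Linking arrays also differ in sex-linked transcripts. Xist was at 12.19 in LT-HSC 4, 11.90 in MPP3 3 and 11.18 in GMP 4, with the Y-linked Eif2s3y at 4.38 or less. In ST-HSC and in MPP3 1 and 2, Xist was at 5.76 or less and Eif2s3y at 9.03 or more. In several comparisons some arrays of the compared populations carry no weight in a set-adjusted change and enter only its SE, and there the arrays that the change rests on are named. The quantile-normalized fit uses all arrays of both populations. A gene or list is said to have risen or fallen only where the set-adjusted fit and, in the same direction, the quantile-normalized fit without sets called it. Gene values are log2 changes ± SE of the set-adjusted fit. For a list, the members called in both fits, the median log2 change and the adjusted p of the list test are given. A further p is given where an estimated correlation between genes ends the call.

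**Figure D1:**
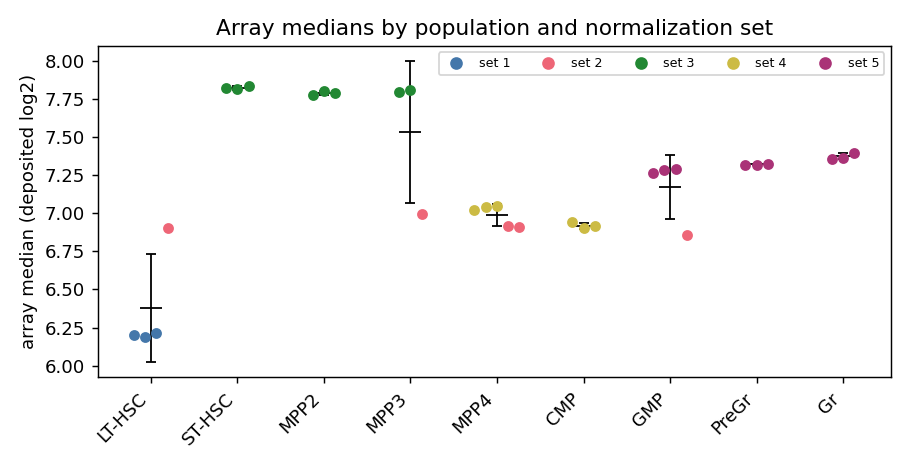
Median of the deposited log2 values of each array (y axis) by population (x axis), with points coloured by normalization set and the bar giving mean ± SD. LT-HSC 4 lies apart from LT-HSC 1, 2 and 3, which have medians of 6.19 to 6.22.

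Genes of cell division were lower in ST-HSC (n = 3) than in LT-HSC (n = 4). In the mitosis list 9 of 23 members (18 adjusted over the list alone) fell (median -1.66, adjusted p = 3.37e-21). Among them were Kif11 (-2.51 ± 0.44), Bub1 (-2.49 ± 0.54), Prc1 (-2.47 ± 0.50) and Ttk (-2.33 ± 0.50), which encode a spindle motor, checkpoint kinases and a spindle midzone protein. The checkpoint kinase gene Bub1b (-1.64 ± 0.37) also fell. The mitosis score, a mean log2 deviation over the list, was -1.50 in ST-HSC. It was -0.81 to -0.53 in LT-HSC 1 to 3 and -0.16 in LT-HSC 4, the array on which the set-adjusted change rests. The DNA replication list was lower (median -0.44, adjusted p = 0.000178, and adjusted p = 0.42 with an estimated correlation), with 0 members called. Tek (-1.64 ± 0.24) and Mecom (-1.38 ± 0.31), a receptor and a transcription factor of stem cells, fell, while the stem cell list was not called in the set-adjusted fit (median -0.11, adjusted p = 0.104) but was lower after quantile normalization (adjusted p = 0.000865). Its score was 1.38 to 1.49 in LT-HSC 1 to 3, 0.81 in LT-HSC 4 and 0.80 in ST-HSC. The lymphoid priming list was higher (median 0.30, adjusted p = 0.0297, and adjusted p = 0.326 with an estimated correlation), with 2 of 26 members (5 adjusted over the list alone), among them Flt3 (1.64 ± 0.35). Without Flt3 that list did not pass (adjusted p = 0.0775), and its direction turned in the planned fit without LT-HSC 4 (adjusted p = 0.767). The sort marker Slamf1 (-2.71 ± 0.42) fell. These changes rest on the 3 ST-HSC arrays, LT-HSC 4 and the MPP3 arrays that link their sets. The planned fit called 18430 genes, 18416 higher and 14 lower. Quantile normalization gave 4596, 2548 and 2048. The set-adjusted fit called 378, 235 higher and 143 lower, of which 162 were also called after quantile normalization. Set-adjusted counts were 199 without ST-HSC 3, 94 without MPP3 1, 224 without MPP3 2, 238 without GMP 2 and 171 without GMP 4. Without LT-HSC 4 or MPP3 3 the contrast could not be fitted. Calls were lost for Bub1, Prc1, Ttk, Bub1b, Mecom and Flt3 without MPP3 1 (adjusted p = 0.0522 to 0.0798), Bub1b and Mecom without ST-HSC 3 (adjusted p = 0.0508 to 0.0512), and Mecom and the lymphoid list without MPP3 2 (adjusted p = 0.0564 to 0.215). Other calls lost were Mecom and Flt3 without GMP 4 (adjusted p = 0.0562 to 0.0675). Without ST-HSC 1, the stem cell list passed (adjusted p = 0.0247).

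MPP2 (n = 3) had lower levels of stem cell genes and higher levels of cell division genes than LT-HSC (n = 4). In the stem cell list 5 of 21 members (7 adjusted over the list alone) fell (median -0.63, adjusted p = 6.84e-09), with Mecom (-2.57 ± 0.31), Tek (-1.64 ± 0.24), Mllt3 (-1.22 ± 0.33) and Procr (-1.06 ± 0.30). Outside the lists Abcg3 (-4.16 ± 0.56), Hacd4 (-2.87 ± 0.39) and Emcn (-2.39 ± 0.50) fell, of which Emcn encodes a sialomucin of endothelium and stem cells. The mitosis list rose in 5 of 23 members (7 adjusted over the list alone, median 0.84, adjusted p = 1.93e-05, and adjusted p = 0.391 with an estimated correlation), such as Plk1 (1.47 ± 0.36), Ube2c (1.43 ± 0.36) and Aurkb (1.38 ± 0.25). The DNA replication list rose (median 0.38, adjusted p = 0.0253, and adjusted p = 0.684 with an estimated correlation), with 1 member called, but its direction turned with the set block (adjusted p = 0.992) and in the planned fit without LT-HSC 4 (adjusted p = 0.475). Mpo (3.96 ± 0.59), the myeloperoxidase gene of primary granules, rose, as did the erythroid genes Zfpm1 (0.99 ± 0.24) and Slc4a1 (0.84 ± 0.19). Relative to all genes Zfpm1 turned to -0.04 with array weights and -0.06 in the planned fit without LT-HSC 4. The erythroid list was not called (median 0.20, adjusted p = 0.257). The interferon response list was lower (median -0.51, adjusted p = 0.00122, and adjusted p = 0.168 with an estimated correlation). The arrays behind these changes are MPP2 1 to 3, LT-HSC 4 and the MPP3 arrays that link their sets. In the planned fit 17787 genes were called, 17711 higher and 76 lower. These numbers were 7343, 4118 and 3225 after quantile normalization. Of 1484 calls in the set-adjusted fit, 897 higher and 587 lower, 916 were also called after quantile normalization. The set-adjusted count was 2255 without MPP2 3, 753 without MPP3 1, 987 without MPP3 2 and 854 without GMP 4. This contrast could not be fitted without LT-HSC 4 or MPP3 3. Calls ended for Mllt3 and Ube2c without MPP3 2 (adjusted p = 0.0671 to 0.0734). That of Procr ended without MPP2 1, MPP3 1 or GMP 4 (adjusted p = 0.0513, 0.123 and 0.072).

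MPP3 (n = 3) carried both granulocyte-monocyte and lymphoid transcripts above LT-HSC (n = 4). The set-adjusted changes compare 1 array with 1, MPP3 3 with LT-HSC 4. In the granulocyte-monocyte and primary granule list 7 of 22 members (10 adjusted over the list alone) rose (median 0.65, adjusted p = 2.04e-06, and adjusted p = 0.052 with an estimated correlation). Among them were Mpo (6.00 ± 0.50), Ctsg (3.30 ± 0.58), Cst7 (2.34 ± 0.66) and Plac8 (1.74 ± 0.31), of which Mpo and Ctsg encode granule enzymes. In the lymphoid priming list 8 of 26 members (13 adjusted over the list alone) rose (median 0.59, adjusted p = 2.07e-07), with Dntt (3.97 ± 0.28), Cd52 (2.35 ± 0.32), Satb1 (2.04 ± 0.33) and Igll1 (1.97 ± 0.37). Dntt encodes the polymerase that adds nucleotides at antigen receptor joints. Stem cell genes fell in 9 of 21 members (14 adjusted over the list alone, median -0.73, adjusted p = 1.61e-12), among them Mecom (-2.60 ± 0.26), Tek (-2.05 ± 0.20) and Mllt3 (-1.08 ± 0.28). Abcg3 (-3.98 ± 0.47), Mmrn1 (-3.24 ± 0.51) and Aldh1a1 (-2.09 ± 0.48) fell as well. The Hox list (median -0.33, adjusted p = 0.0207, and adjusted p = 0.14 with an estimated correlation) and the megakaryocyte list (median -0.23, adjusted p = 0.0418, and adjusted p = 0.41 with an estimated correlation) were lower. Antibody transcripts were higher, with Jchain (6.19 ± 1.48), Igkv19-93 (4.78 ± 0.74) and Igha (3.99 ± 0.62). The markers of B and plasma cells rose (median 0.44, adjusted p = 0.0243, and adjusted p = 0.42 with an estimated correlation), with Pou2af1 (2.47 ± 0.37) and Cd79a (1.35 ± 0.32). Those of T and NK cells rose too (median 0.22, adjusted p = 0.0418, and adjusted p = 0.182 with an estimated correlation), with Thy1 (1.34 ± 0.30) and Il2rb (0.74 ± 0.19). Over all genes the planned fit made 15774 calls, 15661 higher and 113 lower. After quantile normalization there were 5529, 3120 and 2409. In the set-adjusted fit there were 1384, 849 higher and 535 lower, and quantile normalization alone called 908 of them. The set-adjusted count was 860 without GMP 4. Without LT-HSC 4 or MPP3 3 the contrast could not be fitted. Calls ended for Il2rb without GMP 4 (adjusted p = 0.0663), the megakaryocyte list and the T and NK cell list without MPP2 1 (adjusted p = 0.0512 to 0.0545), and the megakaryocyte list without CMP 2 (adjusted p = 0.0526).

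Lymphoid genes were higher in MPP4 (n = 5) than in LT-HSC (n = 4). The set-adjusted changes compare MPP4 4 and 5 with LT-HSC 4. In the lymphoid priming list 9 of 26 members (13 adjusted over the list alone) rose (median 0.73, adjusted p = 1.34e-15). They included Dntt (5.77 ± 0.24), Satb1 (3.41 ± 0.28) and Cd52 (2.76 ± 0.28), where Satb1 encodes a chromatin organizer of lymphoid cells. The list also holds Flt3 (3.35 ± 0.26), the sort marker of MPP4, and without it adjusted p = 2.38e-13. The granulocyte-monocyte list rose in 7 of 22 members (13 adjusted over the list alone, median 0.57, adjusted p = 1.18e-09), with Mpo (5.24 ± 0.43), Ctsg (2.43 ± 0.50), Clec12a (2.39 ± 0.32) and Plac8 (1.84 ± 0.27). Stem cell genes fell in 7 of 21 members (14 adjusted over the list alone, median -0.61, adjusted p = 2.16e-15), with Tek (-2.48 ± 0.17), Mecom (-1.76 ± 0.23), Ctnnal1 (-1.61 ± 0.38) and Mllt3 (-1.58 ± 0.24). Megakaryocyte genes fell in 4 of 19 members (8 adjusted over the list alone, median -0.44, adjusted p = 1.07e-05, and adjusted p = 0.0581 with an estimated correlation), with the platelet glycoprotein gene Gp5 (-1.79 ± 0.40). Outside the lists Tespa1 (3.07 ± 0.47) and Atp8b4 (3.19 ± 0.29) rose, and Abcg3 (-3.72 ± 0.41), Mmrn1 (-3.03 ± 0.44) and Aldh1a1 (-2.53 ± 0.41) fell. The mitosis list rose (median 0.28, adjusted p = 0.00309, and adjusted p = 0.59 with an estimated correlation), with Aurka (1.02 ± 0.22) and Aurkb (0.87 ± 0.18). The DNA replication list rose (median 0.25, adjusted p = 0.0144, and adjusted p = 0.64 with an estimated correlation), with 0 members called, but its direction was reversed in the planned fit. The planned fit called 11963 genes, 11568 higher and 395 lower. Quantile normalization gave 4978, 2753 and 2225. The set-adjusted fit called 570, 269 higher and 301 lower, of which 425 were also called after quantile normalization. With the replicate number as a second block the set-adjusted count was 1050, and the mitosis (adjusted p = 0.927) and replication lists (adjusted p = 0.0869) did not pass. The mitosis median fell to 0.05 with that block. Relative to all genes it fell to 0.01 without MPP4 5, so the set-adjusted rise rests on that array. Mitosis scores were -0.145 or more in MPP4 arrays and -0.164 or less in LT-HSC. The set-adjusted count was 305 without MPP4 4, 1154 without MPP4 5 and 356 without GMP 4. This contrast could not be fitted without LT-HSC 4. Calls were lost for Ctnnal1 and Aurka without MPP4 4 (adjusted p = 0.0715 to 0.152), Ctnnal1 and Gp5 without GMP 4 (adjusted p = 0.0546 to 0.0571), and the mitosis list and the replication list without MPP4 5 (adjusted p = 0.0807 to 0.943).

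The comparisons of MPP2, MPP3 and MPP4 share the LT-HSC arrays, so their calls overlap by construction. In the planned fit 11491 genes were higher and 49 lower in all 3, where independent lists would give 8072 and 0.00853. Simulated unchanged populations that keep the set offsets gave means of 11499 and 7.7 over 20 simulations. The higher count is about what the set offsets give, and the lower count exceeds the highest simulated one, 10. In the set-adjusted fit 80 genes were higher and 117 lower. Independent lists would give 0.52 and 0.24, and the simulation gave 0 and 0.05. After quantile normalization alone the counts were 1532 and 1172. Mecom and Tek fell in each of the 3 comparisons and Mpo rose in each. With the LT-HSC arrays divided between the comparisons after quantile normalization, MPP2 and MPP3 had 1347 to 2352 genes changed the same way over 6 divisions, MPP2 and MPP4 776 to 1677, and MPP3 and MPP4 814 to 1200. With shared arrays these pairs had 4329, 3179 and 3248, and independent lists would give 1034, 929 and 700. In the set-adjusted fit the single LT-HSC array could not be divided, so its share of the overlap is unknown.

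MPP2 (n = 3) had more megakaryocyte and fewer lymphoid and granulocyte-monocyte transcripts than MPP3 (n = 3). Set-adjusted changes here compare MPP2 1 to 3 with MPP3 1 and 2. In the megakaryocyte list 4 of 19 members (9 adjusted over the list alone) rose (median 0.34, adjusted p = 2.11e-09). They included Pf4 (3.05 ± 0.54), Gp5 (1.55 ± 0.30) and F2r (0.83 ± 0.14), genes of platelet granules, platelet surface and the thrombin receptor. The erythroid list was higher (median 0.16, adjusted p = 0.00867, and adjusted p = 0.138 with an estimated correlation), with Icam4 (0.85 ± 0.20). In the granulocyte-monocyte list 7 of 22 members (18 adjusted over the list alone) fell (median -0.69, adjusted p = 2.68e-26), with Ctsg (-3.24 ± 0.37), Clec12a (-3.11 ± 0.24), Ms4a3 (-2.68 ± 0.43) and Mpo (-2.04 ± 0.32). Lymphoid genes fell in 7 of 26 members (19 adjusted over the list alone, median -0.86, adjusted p = 3.65e-23), with Dntt (-2.68 ± 0.18), Satb1 (-2.12 ± 0.21), Cd52 (-2.06 ± 0.21) and Il7r (-1.99 ± 0.33). Igkv19-93 (-4.24 ± 0.48) and Igha (-3.72 ± 0.40) were lower in MPP2. So were the markers of B and plasma cells (median -0.18, adjusted p = 0.0303, and adjusted p = 0.444 with an estimated correlation), T and NK cells (median -0.16, adjusted p = 0.00073) and monocytes (median -0.11, adjusted p = 0.00146, and adjusted p = 0.258 with an estimated correlation). The secondary granule list (median -0.13, adjusted p = 0.00337, and adjusted p = 0.323 with an estimated correlation) was lower, with Cybb (-2.12 ± 0.19), and so was the mature neutrophil list (median -0.15, adjusted p = 0.000361, and adjusted p = 0.127 with an estimated correlation), with Clec4e (-1.42 ± 0.21). Without MPP3 1 the median of the secondary granule list, relative to all genes, turned to 0.01. The interferon list was lower (median -0.24, adjusted p = 3.34e-05, and adjusted p = 0.0637 with an estimated correlation) and the mitosis list higher (median 0.55, adjusted p = 3.82e-10, and adjusted p = 0.209 with an estimated correlation). In the planned fit 26 genes were called, 14 higher and 12 lower. These numbers were 210, 56 and 154 after quantile normalization. Of 217 calls in the set-adjusted fit, 44 higher and 173 lower, 132 were also called after quantile normalization. With set 3 alone the planned fit called 41, 2 higher and 39 lower. Set-adjusted counts were 729 without MPP2 3, 61 without MPP3 1, 119 without MPP3 2 and 42 without MPP3 3, where set 3 alone was fitted. Without MPP3 1 calls ended for Pf4, Gp5, F2r, Icam4, Ms4a3, Mpo and Il7r. They also ended for the erythroid, B and plasma cell, T and NK cell and secondary granule lists (adjusted p = 0.0611 to 0.205 for all). Without MPP3 3 they ended for Gp5, F2r, Icam4 and Mpo (adjusted p = 0.0504 to 0.418). Without MPP2 1 they ended for Icam4 and the B and plasma cell list (adjusted p = 0.0663 to 0.117). Removal also ended the calls of Icam4 without MPP3 2 (adjusted p = 0.323), and the erythroid list and the B and plasma cell list without MPP2 3 (adjusted p = 0.067 to 0.165).

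Against MPP4 (n = 5), MPP2 (n = 3) again had more megakaryocyte and fewer lymphoid transcripts. Set-adjusted changes compare MPP2 1 to 3 with MPP4 4 and 5 through the MPP3 arrays of both sets. The megakaryocyte list rose in 5 of 19 members (9 adjusted over the list alone, median 0.59, adjusted p = 4.16e-06, and adjusted p = 0.0505 with an estimated correlation), with Cd9 (1.42 ± 0.33) and Itga2b (1.02 ± 0.23). The erythroid list was higher (median 0.42, adjusted p = 0.000528). Apoe (2.27 ± 0.26), the apolipoprotein E gene, rose. Lymphoid genes fell in 6 of 26 members (14 adjusted over the list alone, median -0.88, adjusted p = 8.8e-12), with Dntt (-4.48 ± 0.30), Satb1 (-3.49 ± 0.35) and Cd52 (-2.47 ± 0.35). Without the MPP4 sort marker Flt3 (-3.49 ± 0.32) adjusted p = 6.23e-10 for this list. Granulocyte-monocyte genes fell in 3 of 22 members (5 adjusted over the list alone, median -0.68, adjusted p = 3.1e-09), with Irf8 (-1.39 ± 0.22). The chemokine gene Ccl3 (-3.11 ± 0.44) fell, as did Wfdc17 (-3.54 ± 0.55), Cd53 (-2.71 ± 0.49) and Parp8 (-2.16 ± 0.19). The mature neutrophil list (median -0.14, adjusted p = 0.029, and adjusted p = 0.361 with an estimated correlation) and the interferon list (median -0.54, adjusted p = 0.00175, and adjusted p = 0.184 with an estimated correlation) were lower and the mitosis list higher (median 0.51, adjusted p = 0.00459, and adjusted p = 0.607 with an estimated correlation). Over all genes the planned fit made 16813 calls, 16747 higher and 66 lower. After quantile normalization there were 3300, 1749 and 1551. In the set-adjusted fit there were 541, 266 higher and 275 lower, and quantile normalization alone called 230 of them. The set-adjusted count was 1189 without MPP2 3, 185 without MPP3 1, 320 without MPP3 2 and 220 without GMP 4. This contrast could not be fitted without MPP3 3. Calls ended for Cd9 and Itga2b without MPP3 1 (adjusted p = 0.0624 to 0.085), Cd9 and the mature neutrophil list without MPP3 2 (adjusted p = 0.0575 to 0.083), and Cd9, the mature neutrophil list and the mitosis list without MPP4 4 (adjusted p = 0.0711 to 0.449). Others ended for Cd9 and Itga2b without GMP 4 (adjusted p = 0.0612 to 0.0653), Itga2b without MPP4 5 (adjusted p = 0.0794), and the mature neutrophil list without MPP2 1 (adjusted p = 0.0557). Others ended for the mature neutrophil list without MPP2 3 (adjusted p = 0.0957).

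MPP3 (n = 3) had more antibody transcripts than MPP4 (n = 5) and less of several genes of early lymphoid cells. Here the set-adjusted changes compare MPP3 3 with MPP4 4 and 5. Jchain (6.44 ± 1.28), Igkv19-93 (4.56 ± 0.64), Igha (3.48 ± 0.54) and Igkv9-120 (2.42 ± 0.55) rose. Ighm (1.59 ± 0.24) and Pou2af1 (1.63 ± 0.32), an antibody heavy chain and a B cell coactivator, also rose, while the B and plasma cell list was not called (median 0.15, adjusted p = 0.213). Thy1 (1.96 ± 0.26) and Cybb (1.74 ± 0.25) were higher too, of which Cybb encodes a subunit of the phagocyte oxidase. Dntt (-1.80 ± 0.24) and Satb1 (-1.37 ± 0.28) fell, beside Flt3 (-2.00 ± 0.26), the sort marker of MPP4. The lymphoid priming list was lower in the set-adjusted fit (median -0.27, adjusted p = 0.0213, and adjusted p = 0.303 with an estimated correlation) but did not pass without Flt3 (adjusted p = 0.0923) or after quantile normalization (adjusted p = 0.384). Wfdc17 (-3.14 ± 0.44), Ccl3 (-2.37 ± 0.35) and Sema3d (-2.27 ± 0.25) fell as well. The erythroid list was higher (median 0.22, adjusted p = 0.0112, and adjusted p = 0.144 with an estimated correlation), with 0 members called. The granulocyte-monocyte list was not called in the set-adjusted fit (median 0.13, adjusted p = 0.943) but was higher after quantile normalization (adjusted p = 1.95e-06). The planned fit called 10728 genes, 10718 higher and 10 lower. Quantile normalization gave 350, 191 and 159. The set-adjusted fit called 311, 170 higher and 141 lower, of which 76 were also called after quantile normalization. The set-adjusted count was 154 without GMP 4. Without MPP3 3 the contrast could not be fitted. Calls were lost for Igkv9-120, Pou2af1 and Satb1 without MPP4 4 (adjusted p = 0.0501 to 0.057), Igkv9-120 and the lymphoid list without MPP4 5 (adjusted p = 0.0545 to 0.109), and the lymphoid list without GMP 4 (adjusted p = 0.06).

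**Figure D2:**
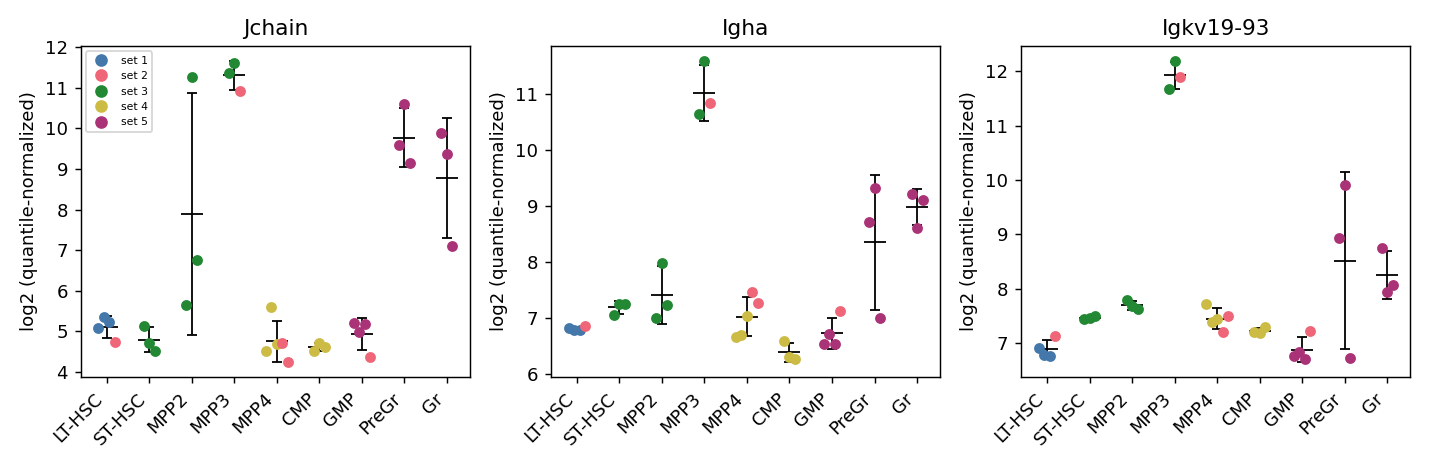
Quantile-normalized log2 level of Jchain, Igha and Igkv19-93 (y axis) on each array by population (x axis), coloured by normalization set, with mean ± SD as a bar. Jchain lies between 10.92 and 11.62 in MPP3 and between 4.24 and 5.59 in MPP4, and 1 MPP2 array reaches 11.28.

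CMP (n = 3) had more granulocyte-monocyte and fewer stem cell transcripts than LT-HSC (n = 4). Set-adjusted changes compare CMP 1 to 3 with LT-HSC 4 through the MPP4 arrays of both sets. In the granulocyte-monocyte list 15 of 22 members (16 adjusted over the list alone) rose (median 1.62, adjusted p = 1.66e-19), with Mpo (7.22 ± 0.52), Ctsg (5.34 ± 0.60), Clec12a (3.70 ± 0.38) and Cst7 (3.68 ± 0.69). In the stem cell list 15 of 21 members (21 adjusted over the list alone) fell (median -1.17, adjusted p = 1.53e-23), with Mecom (-3.28 ± 0.27), Mllt3 (-2.54 ± 0.29), Ndn (-2.41 ± 0.47) and Hlf (-1.67 ± 0.21). The Hox list fell (median -0.33, adjusted p = 0.00201), with Hoxb5 (-1.34 ± 0.32). Abcg3 (-5.04 ± 0.49) and the interferon-inducible GTPase gene Iigp1 (-3.08 ± 0.49) fell, beside a lower interferon list (median -0.73, adjusted p = 0.000528, and adjusted p = 0.138 with an estimated correlation) with Ifih1 (-1.70 ± 0.36). The replication list (median 0.53, adjusted p = 5.47e-05, and adjusted p = 0.389 with an estimated correlation) and the mitosis list (median 0.35, adjusted p = 0.000204, and adjusted p = 0.469 with an estimated correlation) rose, with Rrm2 (1.60 ± 0.37) and Aurkb (1.47 ± 0.22). So did the oxidative phosphorylation list (median 0.30, adjusted p = 0.00073, and adjusted p = 0.438 with an estimated correlation) and the tricarboxylic acid cycle list (median 0.32, adjusted p = 0.009, and adjusted p = 0.205 with an estimated correlation), with Cyc1 (1.16 ± 0.30) and Cs (0.85 ± 0.20). The ribosome biogenesis list (median 0.29, adjusted p = 0.0415, and adjusted p = 0.589 with an estimated correlation) and the mature neutrophil list (median 0.40, adjusted p = 0.00325, and adjusted p = 0.213 with an estimated correlation) rose, the latter with Cxcr2 (3.19 ± 0.52). The oxidative phosphorylation list turned in direction with the replicate block (adjusted p = 0.859). In the planned fit without LT-HSC 4 it turned as well (adjusted p = 0.0723), as did the tricarboxylic acid cycle (0.45), ribosome biogenesis (0.718) and mature neutrophil lists (0.923). Genes of eosinophils, basophils and mast cells rose (median 0.38, adjusted p = 0.000965, and adjusted p = 0.215 with an estimated correlation), with Cpa3 (3.27 ± 0.78), Mcpt8 (2.52 ± 0.58) and Hdc (2.17 ± 0.27). The erythroid transcription factor genes Klf1 (1.14 ± 0.21) and Gata1 (1.07 ± 0.30) rose and Car2 (-1.28 ± 0.21) fell. In the planned fit 12451 genes were called, 12023 higher and 428 lower. These numbers were 4339, 2191 and 2148 after quantile normalization. Of 1108 calls in the set-adjusted fit, 529 higher and 579 lower, 686 were also called after quantile normalization. The set-adjusted count was 684 without MPP4 3, 644 without MPP4 4 and 714 without CMP 1. This contrast could not be fitted without LT-HSC 4. Calls ended for Hoxb5, Cyc1, Cs and Gata1 without MPP4 4 (adjusted p = 0.0505 to 0.118). Without GMP 4 they ended for Hoxb5, Gata1 and the ribosome biogenesis list (adjusted p = 0.0558 to 0.0937). Without MPP4 2 the call of Cyc1 ended (adjusted p = 0.0503). Removal also ended the calls of Cyc1 and Gata1 without MPP4 3 (adjusted p = 0.0526 to 0.0812), Gata1 without CMP 3 (adjusted p = 0.0607), and the mitosis list, the tricarboxylic acid cycle list and the ribosome biogenesis list without MPP4 5 (adjusted p = 0.054 to 0.249). Removal also ended the calls of the ribosome biogenesis list without MPP4 1 (adjusted p = 0.0511).

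From CMP (n = 3) to GMP (n = 4), phagocyte and granule genes rose and megakaryocyte, erythroid and lymphoid genes fell. Set-adjusted changes compare GMP 4 with CMP 1 to 3 through the MPP4 arrays of both sets. The granulocyte-monocyte list rose in 6 of 22 members (9 adjusted over the list alone, median 0.63, adjusted p = 3.19e-07), with Ms4a3 (3.32 ± 0.69) and Igsf6 (2.22 ± 0.49). Without the GMP sort marker Fcgr3 (2.67 ± 0.24) adjusted p = 1.87e-05 for this list. Secondary granule genes rose in 4 of 20 members (5 adjusted over the list alone, median 0.18, adjusted p = 0.000177, and adjusted p = 0.198 with an estimated correlation), with Cybb (3.38 ± 0.30), Hp (2.54 ± 0.31) and Anxa1 (1.94 ± 0.32). Genes of eosinophils, basophils and mast cells rose (median 0.14, adjusted p = 0.00289, and adjusted p = 0.266 with an estimated correlation), with Gzmb (2.89 ± 0.32), and so did those of monocytes (median 0.35, adjusted p = 0.0207, and adjusted p = 0.391 with an estimated correlation), with Adgre1 (1.00 ± 0.19). Megakaryocyte genes fell in 3 of 19 members (6 adjusted over the list alone, median -0.41, adjusted p = 5.67e-07), with Pf4 (-4.10 ± 0.87), F2r (-1.83 ± 0.23) and Itga2b (-1.06 ± 0.23). Erythroid genes fell in 5 of 20 members (10 adjusted over the list alone, median -0.46, adjusted p = 4.31e-08), with Car2 (-2.45 ± 0.21), Aqp1 (-1.90 ± 0.26) and Klf1 (-1.34 ± 0.21). Lymphoid genes fell in 5 of 26 members (9 adjusted over the list alone, median -0.68, adjusted p = 1.68e-11), with Dntt (-4.25 ± 0.29), Flt3 (-2.81 ± 0.31), Gimap6 (-2.34 ± 0.45) and Bcl11a (-1.38 ± 0.22). Slc14a1 (-3.83 ± 0.28), a urea transporter gene, fell. The stem cell list fell (median -0.10, adjusted p = 0.0367, and adjusted p = 0.361 with an estimated correlation), with Meis1 (-1.61 ± 0.35) and Msi2 (-1.45 ± 0.26). Relative to all genes its median turned to 0.07 without MPP4 4. The quiescence-associated list fell (median -0.28, adjusted p = 0.000131), with Txnip (-1.40 ± 0.22). The immediate early list (median -0.54, adjusted p = 0.00292, and adjusted p = 0.479 with an estimated correlation) and the interferon list (median -0.37, adjusted p = 0.0112, and adjusted p = 0.277 with an estimated correlation) fell, the latter with Rtp4 (-1.50 ± 0.32). Over all genes the planned fit made 1533 calls, 1267 higher and 266 lower. After quantile normalization there were 2398, 1137 and 1261. In the set-adjusted fit there were 282, 137 higher and 145 lower, and quantile normalization alone called 221 of them. Set-adjusted counts were 467 without MPP3 3 and 635 without MPP4 5. Without GMP 4 the contrast could not be fitted. Calls ended for Ms4a3, Itga2b, Meis1, Rtp4, the monocyte list, the stem cell list, the immediate early list and the interferon list without MPP4 4 (adjusted p = 0.0513 to 0.678), the stem cell list without MPP4 1 (adjusted p = 0.0661), and the stem cell list without CMP 2 (adjusted p = 0.0701).

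PreGr (n = 3) had more transcripts of secondary granules and fewer of ribosome biogenesis than GMP (n = 4). Their set-adjusted changes rest on set 5, without GMP 4. In the secondary and tertiary granule list 19 of 20 members (20 adjusted over the list alone) rose (median 2.47, adjusted p = 8.24e-36). Among them were Ltf (6.38 ± 0.11), Ngp (6.00 ± 0.40), Camp (5.56 ± 0.24) and Ifitm6 (5.12 ± 0.16), where Ltf encodes lactoferrin and Camp cathelicidin. Mature neutrophil genes rose in 14 of 20 members (15 adjusted over the list alone, median 0.78, adjusted p = 1.17e-13), with Retnlg (5.84 ± 0.25), Ccl6 (3.21 ± 0.14) and Il1r2 (2.72 ± 0.22). Ribosome biogenesis genes fell in 23 of 24 members (23 adjusted over the list alone, median -1.12, adjusted p = 4.51e-22), with Myc (-2.03 ± 0.17), Dkc1 (-1.71 ± 0.21) and Gnl3 (-1.66 ± 0.22). The replication list fell (median -0.42, adjusted p = 0.000528, and adjusted p = 0.464 with an estimated correlation), with Mcm6 (-0.81 ± 0.20). The tricarboxylic acid cycle list (median -0.46, adjusted p = 1.09e-06) and the oxidative phosphorylation list (median -0.23, adjusted p = 0.0158, and adjusted p = 0.607 with an estimated correlation) fell, with Idh3a (-1.19 ± 0.16) and Uqcrc2 (-0.44 ± 0.12). The progenitor gene Angpt1 (-2.35 ± 0.17) and the sort markers Cd34 (-3.22 ± 0.15) and Kit (-1.61 ± 0.11) fell. The quiescence-associated list rose (median 0.56, adjusted p = 3.05e-05), with Trp53inp1 (1.53 ± 0.14) up and Ccnd2 (-1.74 ± 0.13) down. The immediate early list rose (median 0.53, adjusted p = 0.000177, and adjusted p = 0.371 with an estimated correlation), with Atf3 (1.80 ± 0.29), and the interferon list rose (median 0.71, adjusted p = 2.16e-07), with Mx1 (1.42 ± 0.17). Members of the granulocyte-monocyte list went both ways (median -0.07, adjusted p = 0.778), with Cebpe (1.11 ± 0.11) up and Cst7 (-1.48 ± 0.38) down. Markers of other cells were also higher in PreGr. Those of monocytes, macrophages and dendritic cells rose in 11 of 19 members (12 adjusted over the list alone, median 0.84, adjusted p = 1.5e-11), with the antigen presentation genes H2-Aa (3.95 ± 0.33) and Cd74 (2.76 ± 0.32). T and NK cell markers rose (median 0.23, adjusted p = 0.000131), with Cd3d (3.23 ± 0.22) and Cd2 (1.52 ± 0.22). B and plasma cell markers rose (median 0.29, adjusted p = 0.0149, and adjusted p = 0.389 with an estimated correlation), with Ms4a1 (1.52 ± 0.31) and Cd79a (1.31 ± 0.18). Eosinophil and mast cell markers rose (median 0.54, adjusted p = 0.00289, and adjusted p = 0.266 with an estimated correlation), with Ear6 (3.28 ± 0.35) and Prss34 (2.35 ± 0.25). The megakaryocyte list (median 0.11, adjusted p = 0.0145, and adjusted p = 0.323 with an estimated correlation) and the lymphoid priming list (median 0.26, adjusted p = 0.0418, and adjusted p = 0.361 with an estimated correlation) rose, with Cd9 (1.69 ± 0.18) and Lsp1 (3.25 ± 0.22), the latter list not without Flt3 (adjusted p = 0.0524). The stromal list was not called (median 0.10, adjusted p = 0.0944), although Fn1 (4.85 ± 0.14) rose. The planned fit called 1686 genes, 1119 higher and 567 lower. Quantile normalization gave 3257, 1506 and 1751. The set-adjusted fit called 3738, 1697 higher and 2041 lower, of which 3048 were also called after quantile normalization. Within set 5 the planned fit called 4523. Calls were lost for Mcm6 without GMP 4 (adjusted p = 0.0717), the B and plasma cell list, the megakaryocyte list and the lymphoid list without PreGr 2 (adjusted p = 0.0585 to 0.0727), and the lymphoid list without GMP 1 (adjusted p = 0.053). Other calls lost were the lymphoid list without GMP 3 (adjusted p = 0.0502), and the lymphoid list without PreGr 3 (adjusted p = 0.0902).

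Granulocytes (n = 3) had more transcripts of mature neutrophils than PreGr (n = 3) and fewer of primary granules and growth. In the mature neutrophil list 19 of 20 members (20 adjusted over the list alone) rose (median 1.97, adjusted p = 2.11e-20). Among them were Il1b (3.94 ± 0.14), Clec4d (3.76 ± 0.26), Ptgs2 (2.94 ± 0.28) and Cxcr2 (2.73 ± 0.29), which encode a cytokine, a lectin, a cyclooxygenase and a chemokine receptor. Secondary and tertiary granule genes rose in 9 of 20 members (13 adjusted over the list alone, median 0.56, adjusted p = 4.65e-07, and adjusted p = 0.0688 with an estimated correlation), with Arg2 (3.31 ± 0.15), Mmp9 (2.80 ± 0.21), Mmp8 (2.07 ± 0.25) and Mmp25 (1.93 ± 0.14). The granulocyte-monocyte and primary granule list fell in 12 of 22 members (12 adjusted over the list alone, median -0.73, adjusted p = 0.00983, and adjusted p = 0.316 with an estimated correlation), with Ctsg (-2.07 ± 0.33), Elane (-2.00 ± 0.29) and Nkg7 (-2.21 ± 0.33). DNA replication genes fell in 21 of 24 members (22 adjusted over the list alone, median -1.21, adjusted p = 2.64e-16, and adjusted p = 0.0567 with an estimated correlation), with Pola1 (-1.72 ± 0.20), Rrm1 (-1.63 ± 0.21) and Mcm3 (-1.58 ± 0.21). Mitosis genes fell in 19 of 23 members (22 adjusted over the list alone, median -0.89, adjusted p = 1.62e-12, and adjusted p = 0.144 with an estimated correlation), with Cdk1 (-1.47 ± 0.21) and Bub1 (-1.38 ± 0.26). Ribosome biogenesis genes fell in 18 of 24 members (20 adjusted over the list alone, median -0.80, adjusted p = 2.38e-13), with Fbl (-2.03 ± 0.13) and Nop58 (-1.83 ± 0.28). Oxidative phosphorylation genes fell in 15 of 23 members (18 adjusted over the list alone, median -0.67, adjusted p = 3.82e-10, and adjusted p = 0.138 with an estimated correlation), with Etfb (-1.63 ± 0.15) and Ndufb5 (-1.11 ± 0.19). The tricarboxylic acid cycle list fell (median -0.38, adjusted p = 0.000143, and adjusted p = 0.0525 with an estimated correlation), with Fh1 (-1.34 ± 0.20). The glycolysis list was not called (median -0.09, adjusted p = 0.57), and the quiescence-associated list rose (median 0.61, adjusted p = 0.000178), with Trp53inp1 (1.77 ± 0.14) and Tob1 (1.30 ± 0.14). Outside the lists Stfa2 (3.87 ± 0.18) and Dhrs9 (3.65 ± 0.13) rose and Gzma (-2.86 ± 0.19) and Msr1 (-2.66 ± 0.22) fell. Markers of B and plasma cells rose in 6 of 13 members (10 adjusted over the list alone, median 0.59, adjusted p = 0.00204, and adjusted p = 0.271 with an estimated correlation), beside Ebf1 (1.47 ± 0.39), Rag1 (1.29 ± 0.37) and Il7r (1.15 ± 0.29). Megakaryocyte genes rose as a list (median 0.22, adjusted p = 0.0249, and adjusted p = 0.361 with an estimated correlation), with Thbs1 (2.21 ± 0.24) and Clec1b (1.79 ± 0.15). Monocyte markers fell in 7 of 19 members (11 adjusted over the list alone, median -0.72, adjusted p = 0.00223, and adjusted p = 0.266 with an estimated correlation). Eosinophil and mast cell markers fell (median -0.31, adjusted p = 0.0227, and adjusted p = 0.391 with an estimated correlation), with Prg3 (-2.63 ± 0.23). In the planned fit 2004 genes were called, 671 higher and 1333 lower. These numbers were 3832, 1718 and 2114 after quantile normalization. Of 5581 calls in the set-adjusted fit, 2944 higher and 2637 lower, 3831 were also called after quantile normalization. Within set 5 the planned fit called 5607. Without Gr 3 the set-adjusted count was 3717. Calls then ended for Ebf1, Rag1 and the eosinophil and mast cell list (adjusted p = 0.0546 to 0.144). Rag1 also lost its call without PreGr 1 (adjusted p = 0.0648). That list lost its own without GMP 4 or PreGr 2 (adjusted p = 0.09 and 0.0739).

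**Figure D3:**
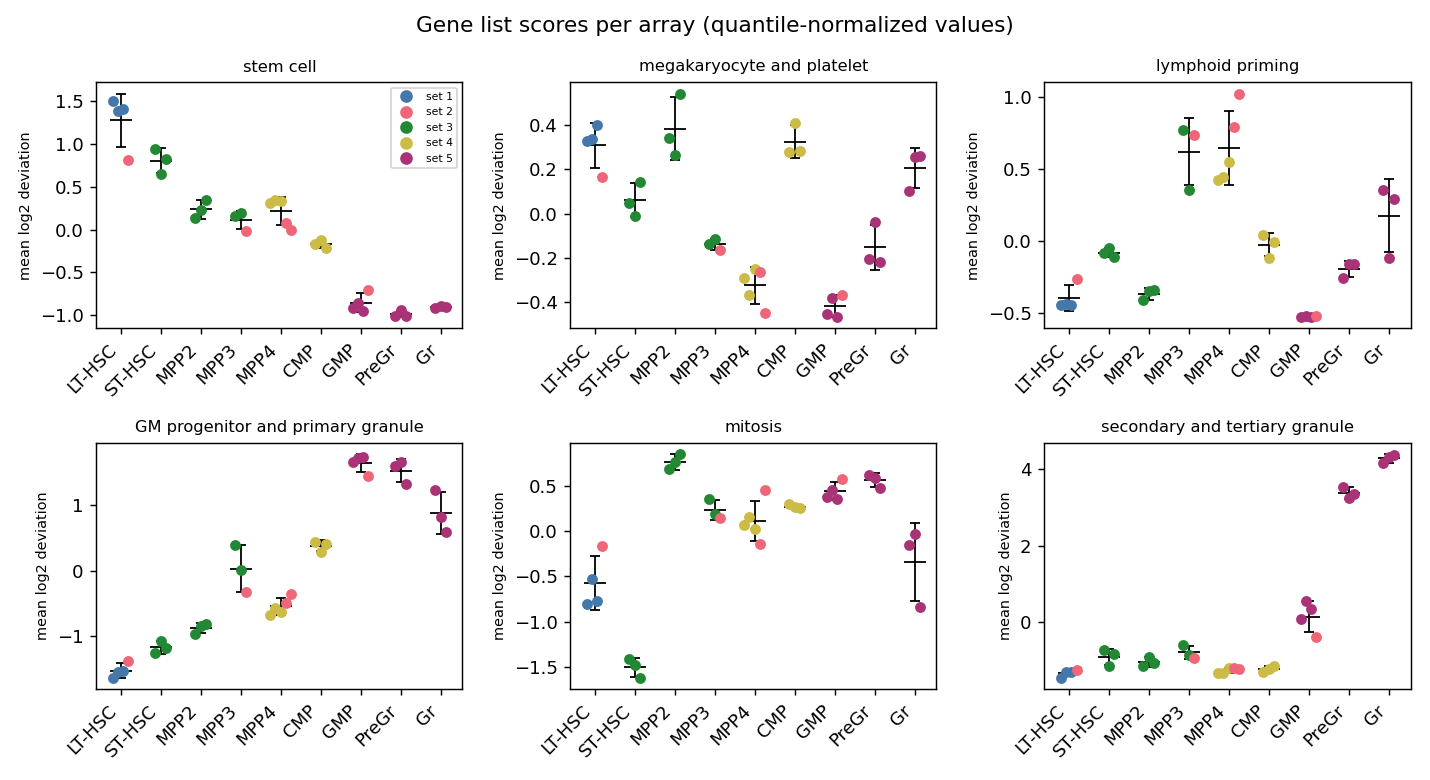
Mean log2 deviation of the genes of 6 lists (y axis) on each array by population (x axis), from quantile-normalized values, coloured by normalization set with mean ± SD as a bar. The stem cell score is 1.27 ± 0.31 in LT-HSC and -0.86 ± 0.11 in GMP, and the secondary and tertiary granule score is 0.14 ± 0.40 in GMP and 4.28 ± 0.11 in Gr.

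**Figure D4:**
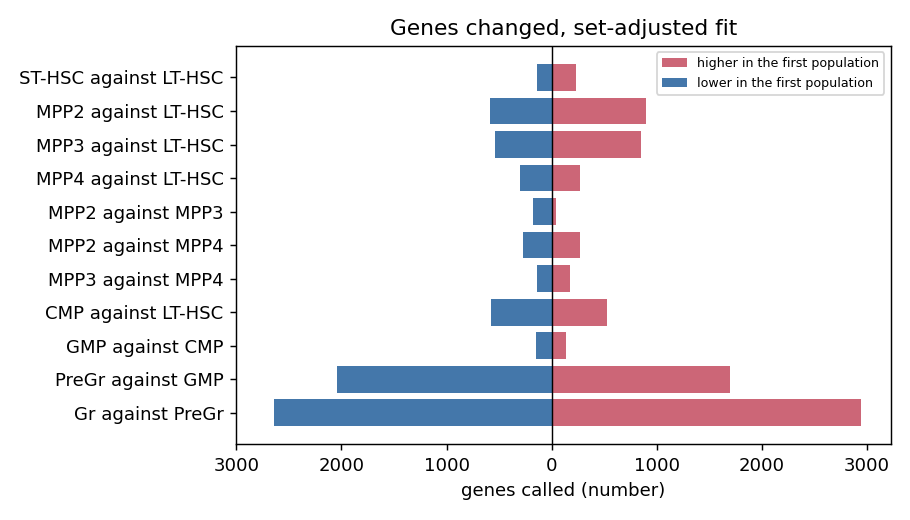
Genes called higher (right) and lower (left) in the first population of each comparison in the set-adjusted fit, as numbers of genes on the x axis. The calls number 5581 for Gr against PreGr and 217 for MPP2 against MPP3.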

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

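A sample far from the others of its population was sought in the groups of 4 and 5 arrays. Its gap to the nearest array, divided by the range of the group, was compared with Dixon's critical value. Over 99 ratios 8 passed, where 4.95 would by chance. The tests of explanations below were chosen after the results were seen.

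LT-HSC 4 stood apart in the median of its deposited gene values, at 7.03 against 6.41 to 6.46 in the others (ratio 0.91). It also did in their SD, at 1.60 against 1.92 to 1.94 in the others (ratio 0.955). After quantile normalization its stem cell score was 0.81 against 1.38 to 1.49 in the others (ratio 0.839). Its lymphoid priming score was -0.26 against -0.44 to -0.43 in the others (ratio 0.929). GMP 4 had a deposited median of 7.03 against 7.41 to 7.47 in the others (ratio 0.861). Its mature neutrophil score was -0.19 against 0.16 to 0.22 in the others (ratio 0.847), and its Hox score -0.26 against -0.49 to -0.46 in the others (ratio 0.899). GMP 3 had a score of B and plasma cell markers of -0.13 against -0.27 to -0.25 in the others (ratio 0.883).

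LT-HSC 4 and GMP 4 belong to set 2, and the other arrays of their populations to sets 1 and 5. The pattern weighed is that most called genes were higher in the population of the brighter set, 18416 of 18430 in ST-HSC against LT-HSC. MPP3 1 and 2 lay 0.761 (log2) above MPP3 3 in median, a gap within 1 population, and after quantile normalization 2548 of 4596 calls were higher, so separate normalization remains as an explanation and may account for the pattern. A rise of most transcripts stays open and cannot be told apart from it. The medians of MPP2 and MPP3 within set 3 differed by -0.0142, but normalization within a set fixes that value. LT-HSC 4 is also the array on which the set-adjusted comparisons with LT-HSC rest, and its lower stem cell score enters each of them; a difference between its cells and those of LT-HSC 1 to 3 was not tested.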

How the results depend on the processing

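The number of genes called changed with the treatment of the sets of arrays, with array weights and with fits of the compared populations alone. Counts are given for the comparisons in the order ST-HSC, MPP2, MPP3 and MPP4 against LT-HSC, MPP2 against MPP3 and MPP4, MPP3 against MPP4, CMP against LT-HSC, GMP against CMP, PreGr against GMP and Gr against PreGr, and last for genes changed alike in the MPP populations. Quantile normalization gave 4596, 7343, 5529, 4978, 210, 3300, 350, 4339, 2398, 3257, 3832 and 2704. Centring gave 8648, 11206, 10652, 9312, 64, 2297, 193, 5368, 2317, 3082, 3515 and 6683, and centring with scaling 5323, 8478, 6581, 5899, 218, 3812, 478, 4124, 2040, 3074, 4463 and 3596. The set block, added after the data were seen, gave 116, 1603, 1235, 345, 162, 217, 91, 909, 230, 4791, 5835 and 130, and the set-adjusted fit 378, 1484, 1384, 570, 217, 541, 311, 1108, 282, 3738, 5581 and 197. Testing all probes, which adds probes to the test, moved the counts beyond 1.5 times to 31610 (ST-HSC against LT-HSC), 30378 (MPP2 against LT-HSC), 26422 (MPP3 against LT-HSC), 19232 (MPP4 against LT-HSC), 26952 (MPP2 against MPP4) and 18614 (overlap of the MPP populations). The dim filter, which leaves 14642 genes over log2 7.23 in at least 1 population, moved them to 10501 (MPP3 against LT-HSC), 7004 (MPP4 against LT-HSC), 6818 (MPP3 against MPP4) and 6683 (overlap of the MPP populations). Array weights gave 294 (MPP2 against MPP3), 18488 (MPP3 against MPP4), 14197 (GMP against CMP), 6336 (PreGr against GMP) and 6406 (Gr against PreGr), and fits of the compared populations alone 2 (MPP2 against MPP3), 31 (MPP3 against MPP4), 1086 (PreGr against GMP) and 4249 (Gr against PreGr). Within 1 set, also added later, the counts were 41 (MPP2 against MPP3), 4523 (PreGr against GMP) and 5607 (Gr against PreGr). Trend and robust moderation and the mean of a gene's probes moved no count beyond 1.5 times. Beyond the numbers of probes, genes or arrays in a test, the cause was not tested.

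With the replicate number as a block the planned counts were 17936, 17339, 15217, 12022, 33, 15439, 9339, 12379, 1618, 1968, 2280 and 11515. Within replicates 1 to 3 of 6 populations and after quantile normalization, a block gave 8250 (MPP4 against LT-HSC), 8033 (CMP against LT-HSC), 5010 (GMP against CMP), 4437 (PreGr against GMP) and 6358 (Gr against PreGr). Without the block the same arrays gave 8411, 8221, 5217, 4564 and 6508. A replicate block in the set-adjusted fit of MPP4 against LT-HSC gave 1050 genes instead of 570. There the mitosis and DNA replication lists lost their calls, and the block changed no other call named in that comparison.

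Leaving out each array of the planned fit in turn gave 17768 to 18264, 16901 to 17485, 13718 to 18442 and 10598 to 13033 genes for ST-HSC, MPP2, MPP3 and MPP4 against LT-HSC, and 9834 to 14235 for CMP against LT-HSC. For MPP2 against MPP3 the range was 11 to 47, lowest without MPP2 3 and highest without MPP3 3, and for MPP2 against MPP4 15374 to 16868. For MPP3 against MPP4 it was 203 to 17424, lowest without MPP3 1 and highest without MPP3 3, with 226 without MPP3 2. For GMP against CMP it was 648 to 4575, lowest without CMP 2 and highest without GMP 4, with 733 to 825 without any other array of these populations. The lowest counts of PreGr against GMP (1100 to 1959) and Gr against PreGr (990 to 2041) came without PreGr 1 and Gr 3, and the latter was 1288 without PreGr 2. The overlap of the MPP populations ranged from 10250 to 12575.

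The 217 gene results named kept their direction and call in 10046 of 10472 values under alternatives, and the 97 list results in 4228 of 4583. Most of these values leave out 1 array, which often had no weight in the contrast, so they say little of stability. Genes were also named only where quantile normalization called them, and 21 results were left out after such values were seen. Part of the agreement follows from that choice. Genes kept direction and call in 195 of 217 in the planned fit, 201 of 217 with the set block, 181 of 217 in fits of the compared populations alone and 196 of 217 with the dim filter. All 217 passed it, but 7.23 lies below set 3 medians, so background is not excluded. Changes of dimmer genes are measured less well. Lists kept direction and call in 86 of 97 in the planned fit, 93 of 97 after quantile normalization and 40 of 97 with an estimated correlation. A call after quantile normalization was itself a condition for saying that a list rose or fell, so that value was largely fixed. Of the sort marker levels, 43 of 81 moved by more than their SD after quantile normalization. For 1 gene result the direction relative to all genes reversed, Zfpm1 in MPP2 against LT-HSC, at -0.0377 with array weights and -0.0592 in the planned fit without LT-HSC 4. DNA replication genes in MPP4 against LT-HSC reversed to a median relative to all genes of -0.0661 in the planned fit, with centring and with an estimated correlation, -0.0484 with the replicate block, and -0.179, -0.119, -0.103, -0.098, -0.0789, -0.0484, -0.0221 and -0.0214 without single arrays of the planned fit. In MPP2 against LT-HSC their test reversed with the set block (-0.0565) and in the planned fit without LT-HSC 4 (median 0.0416). Without LT-HSC 4 the planned tests also reversed for lymphoid priming in ST-HSC (median 0.26) and, in CMP, for oxidative phosphorylation (-0.174; -0.0761 with the replicate block), the tricarboxylic acid cycle (-0.0213), ribosome biogenesis (0.0698) and mature neutrophil genes (0.361). In some of these the median kept its sign while the test, which weighs all members, changed it. The median alone turned in the set-adjusted fit for stem cell genes in GMP against CMP without MPP4 4 (0.0699) and secondary granule genes in MPP2 against MPP3 without MPP3 1 (0.00806), and with the replicate block for megakaryocyte genes in PreGr against GMP (-0.01). The median of mitosis genes in MPP4 against LT-HSC fell to 0.0112 without MPP4 5. The uncalled granulocyte-monocyte list reversed in MPP3 against MPP4 with the set block (0.0115) and without MPP4 4 (0.0374, the lowest of up to 0.245 without single arrays), and in PreGr against GMP with centring and scaling (-0.0564) and without PreGr 3 (-0.0367, or -0.0653 in the planned fit, with values down to -0.111 without single arrays). The uncalled glycolysis list reversed in Gr against PreGr with centring and scaling (0.255). The cause was not tested.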

Other observations

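The following families were chosen after the data were seen. For the first 4 families below, the directions printed held under all 6 scalings tried, but not those of the olfactory receptor genes. Some set-adjusted calls in other comparisons did not hold either. Histone genes, called lower in ST-HSC than in LT-HSC and in MPP3 than in MPP4, were lower under 5 and 2 of the scalings. Schlafen genes, called lower in ST-HSC than in LT-HSC and in MPP2 than in MPP4, were lower under 2 in each. Genes of replication-dependent histones were higher in MPP2 than in LT-HSC, with 6 of 26 called (median 0.93, adjusted p = 0.000912, and adjusted p = 0.426 with an estimated correlation), and in CMP than in LT-HSC, with 11 called (median 1.09, adjusted p = 4.52e-12, and adjusted p = 0.138 with an estimated correlation). They were lower in Gr than in PreGr, with 19 called lower and 1 higher (median -0.86, adjusted p = 4.75e-06, and adjusted p = 0.314 with an estimated correlation). Genes of interferon-inducible GTPases, the Gbp and Irg families that act against intracellular microbes, were lower than in LT-HSC in MPP2 (median -1.86, adjusted p = 4.66e-06), MPP3 (median -1.26, adjusted p = 0.000425, and adjusted p = 0.0568 with an estimated correlation), MPP4 (median -0.84, adjusted p = 2.25e-05) and CMP (median -1.33, adjusted p = 8e-07). In ST-HSC they did not pass (median -0.46, adjusted p = 0.0921). Gimap genes, which encode GTPases of lymphocytes, were lower in MPP2 than in LT-HSC (median -1.02, adjusted p = 0.000137, and adjusted p = 0.138 with an estimated correlation) and MPP3 (median -0.66, adjusted p = 4.15e-07). The Schlafen genes rose in PreGr over GMP in 5 of 7 (median 2.82, adjusted p = 2.86e-08). As a control, 1015 olfactory receptor genes in PreGr against GMP had a median of 0.01 (adjusted p = 0.811). These genes passed in MPP2 against MPP4 (median 0.15, adjusted p = 0.00197). They also did in MPP3 against MPP4, within set 2 (median 0.09, adjusted p = 0.00443). Neither passed with an estimated correlation (adjusted p = 0.138 and 0.151) or after quantile normalization alone (0.572 and 0.751). The set-adjusted list test at a preset correlation thus calls shifts as small as these.

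All tests of explanations in this part other than the splits of arrays were chosen after their results were seen. MPP3 carried immunoglobulin transcripts, with a mean over 7 genes of 10.07 (log2, quantile-normalized) against 6.22 in MPP4 and 7.16 in MPP2, where MPP2 2 reached 8.41. PreGr arrays lay at 7.33 to 8.85 and Gr arrays at 7.39 to 8.47. The sets of arrays are argued against, because the lowest MPP3 array lay 1.82 and 3.16 above the highest other array of its own set in sets 3 and 2. Antibody-secreting cells in the sort are a candidate explanation. Of 12 plasma cell genes other than immunoglobulins, 3 were called higher in MPP3 than in MPP4 (Tent5c, Ell2 and Derl3), with a mean of 0.46 ± 0.15 and p = 0.00014 for the set (0.0252 with an estimated correlation). Sdc1 (-0.37), Sec11c (-0.18) and Fkbp11 (-0.16) were not called, 4 of the genes already exceeded log2 8 in MPP4, and 1 is in the fixed list of B and plasma cell markers. The B220 antibody of the lineage gate would remove B cells but not plasma cells that lack it, and transcription of these genes by MPP3 cells themselves stays open, untested.

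ST-HSC had a mitosis score of -1.50 against -0.57 in LT-HSC, -0.70 in LT-HSC 1 to 3 and -0.16 in LT-HSC 4. An offset between sets as the cause is argued against, because MPP3 1 and 2, of the set of ST-HSC, scored 0.122 above MPP3 3, where a lower score was needed (SD 0.11). That speaks to sets 2 and 3 alone, since set 1 holds LT-HSC 1 to 3 and no other population. Cycling MPP2 cells in the LT-HSC arrays as the whole cause are argued against as well. They would have to make up 23.2 percent, which by itself brings Mpo to 8.38, Car1 to 9.42 and Cd48 to 7.73 in LT-HSC, where 6.68, 7.49 and 6.80 were measured. These and Tespa1 (4 genes) lay below that level by more than 2 SE after quantile normalization, Mpo alone also in the set-adjusted fit, and the LT-HSC gate excludes CD48-positive cells such as MPP2. LT-HSC 4, with the highest mitosis score, had 6.46, 7.76 and 7.60, close to that level in Cd48. Taken by itself this array would need 40.1 percent and 9.17, 10.21 and 8.53. The 50 genes at least 4-fold higher in MPP2 than in ST-HSC differed by 0.912 where 0.946 was needed, but 44 of them follow the mitosis score. The other 6, Xist among them, differed by 0.545 ± 0.936 where 0.931 was needed. A smaller share of cells that divide more than MPP2 stays open. A sex difference alike in all populations is argued against. Arrays with Xist and without Eif2s3y differed in score from arrays without Xist by -0.0841 ± 0.127 over 4 other populations (mean ± SE), where 0.933 was needed. MPP2, in 1 set, had -0.0058. In LT-HSC, array 4 scored 0.644 above array 1, of another set, so a sex effect there alone stays open. A lower rate of division in ST-HSC stays open, untested.

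Xist followed the replicate number in LT-HSC, MPP4, CMP, GMP, PreGr and Gr, at 5.07 to 5.99 in replicate 1, 9.69 to 11.40 in replicate 2 and 8.34 to 10.19 in replicate 3. ST-HSC, MPP2 and MPP3 had other orders. The exact probability that at least 6 of 9 populations share 1 order is 0.00681, so same-numbered arrays of these 6 may hold RNA of the same pools of mice. Of the other 13 arrays, LT-HSC 4, MPP2 2, MPP3 3, MPP4 4 and GMP 4 had Xist at 11.18 or more and Eif2s3y at 4.38 or less. The 8 others, ST-HSC 1 to 3 and MPP3 1 and 2 among them, had Xist at 5.82 or less and Eif2s3y at 9.02 or more, so the contrast of ST-HSC with LT-HSC 4 and that of MPP3 between sets 2 and 3 also part arrays by these transcripts.

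Other splits of the same arrays were counted for each comparison, the real one included, and splits that the set block turns into the same contrast were counted once. Where the populations lie in different sets, the set offsets alone give large planned counts. Simulated unchanged genes were called there in numbers from 1841 in GMP against CMP to 18834 in ST-HSC against LT-HSC. In these comparisons the splits of the planned fit do not speak to the populations. They gave ST-HSC against LT-HSC (1 of 35, 18430 genes, highest other 16806), MPP2 against LT-HSC (1 of 35, 17787 genes, highest other 16378), MPP4 against LT-HSC (1 of 100, 11963 genes, highest other 11647), MPP2 against MPP4 (1 of 56, 16813 genes, highest other 6534), MPP3 against LT-HSC (2 of 35, 15774 genes, highest other 17264), MPP3 against MPP4 (4 of 56, 10728 genes, highest other 14297), CMP against LT-HSC (2 of 35, 12451 genes, highest other 13652) and GMP against CMP (2 of 35, 1533 genes, highest other 6007), and, for drawn splits of 4 populations, the overlap of the MPP populations (3 of 100, 11540 genes, highest other 15032). For MPP4 against LT-HSC 100 of 126 splits were drawn. Of the 16 splits that part its 4 same-numbered pairs, 1 gave as many genes in the planned fit (highest other 11647) and 2 in the set-adjusted fit (570, highest other 570, the real contrast with its sign turned), and these are too few for a share under 0.05. For GMP against CMP the highest other split set GMP 1 to 3 against CMP and GMP 4, which follows the sets and called several times the real count; the set-adjusted value was 282. In ST-HSC, MPP2 and CMP against LT-HSC the highest other split set LT-HSC 1 to 3 apart, which also follows the sets. In PreGr against GMP, where 0 simulated unchanged genes were called, chance can be excluded for the planned fit (1 of 35, 1686 genes, highest other 1494). With the set adjustment the contrast sets PreGr 1 to 3 against GMP 1 to 3, within set 5 (1 of 25, 3738 genes, highest other 1792). GMP 4 carries no weight there, and splits of 3 arrays against 3 are too few for a share under 0.05. These set-adjusted splits therefore decide nothing. If the replicate number pairs these arrays, as the Xist order leaves open, the splits that part the pairs are too few. The splits of the planned fit ignore such pairs as well. In the other comparisons between sets a single array enters the set-adjusted contrast with full weight, LT-HSC 4, MPP3 3 or GMP 4. There no split tells a difference between populations from what is particular to that array, so these splits decide nothing about the populations. They gave ST-HSC against LT-HSC (1 of 34, 378 genes, highest other 12), MPP2 against LT-HSC (1 of 34, 1484 genes, highest other 950), MPP3 against LT-HSC (1 of 29, 1384 genes, highest other 15), MPP4 against LT-HSC (1 of 95, 570 genes, highest other 481), MPP2 against MPP4 (1 of 55, 541 genes, highest other 540), MPP3 against MPP4 (1 of 45, 311 genes, highest other 220), CMP against LT-HSC (1 of 34, 1108 genes, highest other 11) and GMP against CMP (1 of 34, 282 genes, highest other 15). In MPP3 and MPP4 against LT-HSC and in PreGr against GMP, 1 other split was the real contrast with its sign turned, such as GMP 1 to 3 against PreGr with GMP 4. The 10 splits of MPP2 against MPP3 and of Gr against PreGr are too few for a share under 0.05. In Gr against PreGr, 1 of them gave as many genes in the planned fit (2004, highest other 1). In the set-adjusted fit 1 did (5581, highest other 19). In MPP2 against MPP3, 2 did in the planned fit (26, highest other 243) and 2 in the set-adjusted fit (217, highest other 770). The highest put MPP2 1, MPP2 2 and MPP3 3 together. The set adjustment gives MPP3 3 no weight, so there only MPP2 3 changes sides.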
